A study of Homo sapiens and Mus musculus with 12 samples.

How the data were processed

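The series holds 12 CUT&RUN libraries from pancreatic ductal adenocarcinoma (PDA) cells. CUT&RUN directs a nuclease to chromatin through an antibody and sequences the released fragments. Per the labels, 8 libraries came from HPAF-II, an established human PDA cell line carrying HA-tagged SPDEF. Of these, 3 used an antibody against the HA tag, 3 an antibody against GATA6, 1 an IgG control and 1 an antibody against H3K4me3. The other 4 came from FC1245, a mouse PDA line carrying HA-tagged mouse Spdef, with 3 HA libraries and 1 IgG library. Per the labels' protocols, libraries were made with the CUTANA ChIC/CUT&RUN kit and the NEBNext Ultra II kit.

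The submitters' processing notes name Bowtie2 2.4.4, SAMtools 1.14, MACS2 2.2.7.1 and deepTools, and the builds hg19 and mm10; what each did is not given in the sources used here. The deposited data used here are 3 peak lists, 1 per target, each giving the chromosome, start and end of a peak. They carry no score, height or p-value. Each was assigned to its target and cell line from its name, which gives no replicate number, and from chromosome lengths. Whether and how the 3 libraries of a target were combined is not given in the sources used here. Nor are the control, the threshold and any excluded regions. Each list is therefore 1 measurement without replicate error, and the sequencing depth behind it is unknown. A longer list can reflect deeper sequencing, a better antibody or more binding. Peak lists of the IgG and H3K4me3 libraries were not analysed here, so no control background stands beside the peak counts.

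The build was checked against chromosome lengths. In the human lists 0 peaks ended past an hg19 chromosome, against 29 GATA6 and 18 SPDEF peaks past an hg38 chromosome. In the mouse list 0 peaks ended past an mm10 chromosome and 10 past an mm39 chromosome, and 1 peak lay on an unplaced sequence. Positions are printed counting from 1.

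Overlap was counted as at least 1 bp shared. The number of SPDEF peaks overlapping GATA6 peaks was compared with 1000 random placements of the SPDEF peaks on their own chromosomes outside centromere bands, widths kept, with a one-sided permutation p whose smallest possible value is 0.000999. Distances between midpoints used the same placements. Random placement does not keep peaks in open chromatin. Median widths were compared by two-sided permutation tests with 100000 resamples, whose smallest possible p is 1e-05. Since the lists have no score, width took the place of the planned score. Peaks are not replicates, so these p-values describe the lists and not the spread between cultures. Shares carry 95% Wilson intervals and observed to expected ratios carry exact 95% Poisson intervals. All intervals cover counting error only.

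Peaks per chromosome and per cytogenetic band were compared with the number given by length. Bands were tested with an exact upper Poisson p and Benjamini-Hochberg adjustment over 862 human or 403 mouse bands, at an adjusted p threshold of 0.05. The Poisson p treats peaks as independent, and peaks cluster, so these p-values are too small. A list of 12 human bands was fixed in advance. Bands came from circlize 0.4.16 and chromosome lengths from GenomeInfoDb 1.38.1 in R 4.3.3. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

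The gene table used is of GRCh38.p14, a different build from the peaks, so peaks were not assigned to genes. Genes were tied to bands by band name only, all 862 hg19 band names being present in both builds. Of 293 entries in 11 gene lists fixed in advance, 292 had a band. Entries were matched by symbol or, failing that, by synonym, without a further check. A synonym can belong to another gene, and ANG4 of the goblet cell list, placed in 20p13, may be such a case. For each gene list, peaks per Mb in its bands were compared with 10000 random lists of as many protein-coding genes, two-sided, with adjustment over the 11 lists. Random lists matched the number of genes and not the number of bands. For a list whose members share bands, the p-values may therefore be too small. This band-level test was chosen after seeing the data, as were stitching of peaks within 12.5 kb into clusters, the counts within 1 Mb of centromere bands and the comparison of chromosomes in 5 Mb windows. A band holds many genes, so a band count says nothing about a single gene.

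Named peaks followed a rule fixed before the data were examined: the 5 widest of each list, the 10 shared SPDEF peaks with the smallest sum of width ranks, and the 5 widest SPDEF peaks with no GATA6 peak within 10 kb. Those on chromosome Y are not reported. Named bands were the 10 with the highest ratio among those past the threshold with at least 5 peaks, and the 12 fixed bands. Clusters and peaks with matching edges were named after their values were seen.

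The procedures were tested on simulated data. With 29.8% of 2775 peaks planted on GATA6 peaks, 30.1% were recovered on average, and 3 of 100 sets without planted overlap gave p under 0.05. Those sets were drawn by the same random placement as the test, so they check only the calculation. Of 40 bands raised 4-fold, 97.9% were recovered at the size of the GATA6 list and 70.3% at the size of the SPDEF list. Only bands with at least 3 expected peaks were raised, and simulated peaks were independent. Recovery in smaller bands or with clustered peaks was not measured. Of 100 pairs of width samples without a difference, 4 gave p under 0.05.

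Alternatives covered the overlap rule, stricter lists by width, other random placements, chromosomes left out, merging of peaks within 500 bp and other expectations for bands. Location relative to genes, gene lists near peaks, genes shared between species and motifs were planned and not run, since each needs a genome or annotation of the peaks' own build.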

Results

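The series mapped where SPDEF, an ETS-family transcription factor of secretory epithelia, binds in human and mouse PDA cells. GATA6, a zinc-finger factor used as a marker of the classical PDA subtype, was mapped in the human line. The GATA6 list held 10670 peaks covering 5162.59 kb of hg19, or 3.45 peaks per Mb. The SPDEF list held 2775 peaks covering 949.8 kb, or 0.896 peaks per Mb. The mouse Spdef list held 5719 peaks covering 3215.11 kb of mm10, or 2.10 peaks per Mb. Each target had 3 libraries but its list has no replicate values, so no difference between lists could be set against replicate spread. Depth is unknown, and list lengths do not measure how much of a factor was bound.

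Peaks were short in all lists. The median width was 346 bp for GATA6 (quartiles 235 and 641), 268 bp for SPDEF (208 and 391) and 437 bp for mouse Spdef (292.5 and 728). GATA6 peaks were wider than SPDEF peaks by 78 bp at the median, mouse Spdef peaks wider than human SPDEF peaks by 169 bp and wider than GATA6 peaks by 91 bp. Each permutation p was 1e-05, the smallest that 100000 resamples can give. Peaks narrower than 100 bp numbered 319, 134 and 186 in the GATA6, SPDEF and mouse lists, among them 5, 4 and 4 of 1 bp.

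The HPAF-II lists address whether SPDEF and GATA6 occupy the same sites. Of the 2775 SPDEF peaks, 1796 overlapped a GATA6 peak (64.7%, 95% Wilson interval 62.9 to 66.5). Random placement gave 11.3 on average and at most 21, so the observed number was 159 times the random mean (permutation p = 0.000999, the smallest possible). From the other side, 1717 of 10670 GATA6 peaks overlapped an SPDEF peak (16.1%, 15.4 to 16.8), and 8953 did not. The remaining 979 SPDEF peaks had no overlapping GATA6 peak. Both antibodies were used on cells carrying HA-tagged SPDEF, so the GATA6 list does not describe cells without the tagged factor.

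The SPDEF peaks without an overlap were sorted by distance to the nearest GATA6 peak, and no random value was computed for them alone. Edges were within 10 kb for 357 peaks, between 10 and 100 kb for 361 and farther for 261 (9.41% of all SPDEF peaks). Over all 2775 SPDEF peaks, overlapping ones included, the median distance between midpoints was 206.5 bp, against 158019 bp at random (permutation p = 0.000999, the smallest possible). Since 64.7% of the peaks overlapped, this median and its p-value largely restate the overlap. The shares below are over all SPDEF peaks too. Within 1 kb of a GATA6 midpoint lay 70.1% of SPDEF midpoints, against 0.883% at random, and within 10 kb 77.5% against 6.81%. Within 100 kb the share was 90.6%, against 39.0% for placement on the chromosome and 89.9% for moves of 10 to 100 kb. An SPDEF peak on a GATA6 peak stays within about 100 kb of it after such a move. The 89.9% is thus largely set by the size of the moves and is no comparison value at that distance.

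**Figure D1:**
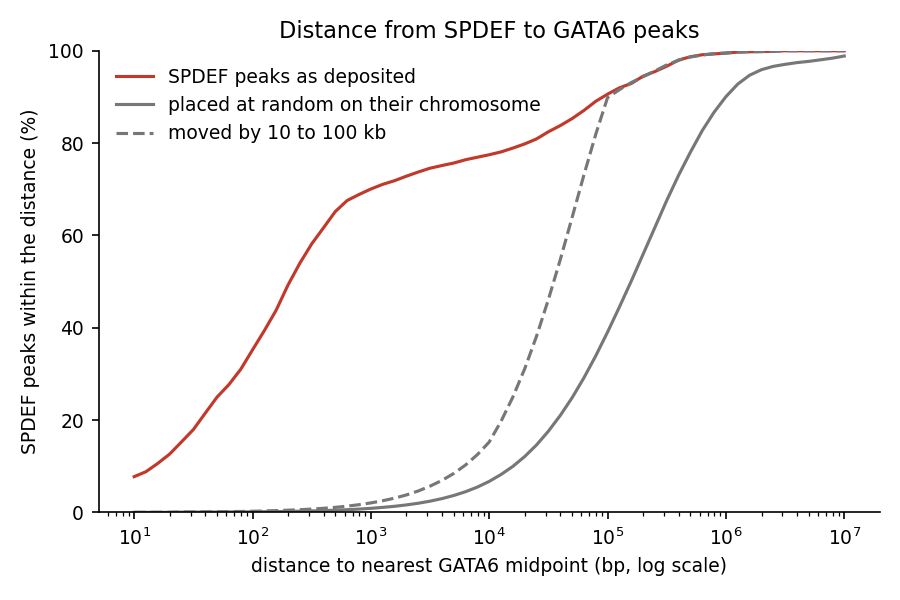
Cumulative share of the 2775 SPDEF peaks (y axis, percent) by distance from their midpoint to the nearest GATA6 midpoint (x axis, bp, log scale). The red line holds the deposited peaks, 70.1% of them within 1 kb; the solid grey line is the mean of placements on the same chromosome, 0.883% within 1 kb, and the dashed line the mean of moves of 10 to 100 kb, 2.05% within 1 kb.

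Overlap rose with width in both lists. From the narrowest to the widest quartile of width, the share of SPDEF peaks with a GATA6 peak was 52.3%, 65.1%, 68.0% and 73.4%. The share of GATA6 peaks with an SPDEF peak was 7.57%, 13.5%, 18.3% and 25.05%. Shared SPDEF peaks had a median width of 286 bp against 241 bp for the rest, and shared GATA6 peaks 494 bp against 326 bp (permutation p = 1e-05 for each, the smallest possible). With midpoints within 1 kb counted as shared, the differences were 33 bp and 98 bp (permutation p = 1e-05 for each, the smallest possible). Counting 1 bp as shared can favour wide peaks by construction, and that rule gave the GATA6 difference of 168 bp. A rule that at least 50% of both peaks be covered excludes GATA6 peaks much wider than their SPDEF peak by construction. Under it the SPDEF difference was 75 bp (permutation p = 1e-05, the smallest possible) and the GATA6 difference 20 bp (permutation p = 0.0902).

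**Figure D2:**
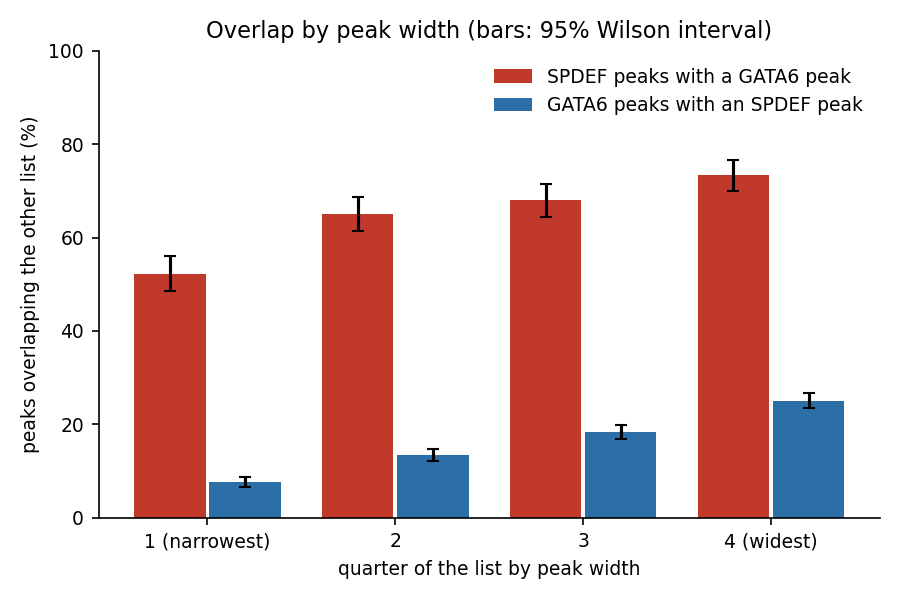
Share of peaks overlapping the other HPAF-II list (y axis, percent) in quartile groups of each list by peak width (x axis). Bars are shares, with 95% Wilson intervals; SPDEF peaks go from 52.3% to 73.4% and GATA6 peaks from 7.57% to 25.05%.

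The shared peaks with the smallest sum of width ranks included 20q11.23 (chromosome 20, 34673008 to 34674365), 11q24.1 (chromosome 11, 121336449 to 121337878) and 7q34 (chromosome 7, 142505965 to 142507104). A pair in 12q13.13 (chromosome 12, 53319119 to 53320091 and 53320253 to 53321269) overlapped the same GATA6 peak of 2763 bp (53318477 to 53321239). Of the 10, 5 others lay on the mitochondrial genome, in 1p36.33 at positions 564522 to 566895 and 567145 to 570269, in 11p15.4 at 10529451 to 10531545, and beside the chromosome 18 centromere at 18518397 to 18520280. Those in 1p36.33 and 11p15.4 had both edges within 10 bp of their GATA6 peaks. Whether they mark sites of the factors or signal set by the reference sequence was not examined. The widest SPDEF peaks with no GATA6 peak within 10 kb lay in 14q11.2 (chromosome 14, 21149985 to 21151311), 11p15.4 (chromosome 11, 6495030 to 6496139), 14q24.1 (chromosome 14, 69864825 to 69865726) and 1p13.3 (chromosome 1, 109968425 to 109969318). The mitochondrial peak was the widest of each list, at 16407 bp for GATA6, 16522 bp for SPDEF and 15893 bp for mouse Spdef. The next widest GATA6 peaks lay in 12q21.1 (8036 bp), 12q15 (3274 bp), 1p36.33 (3120 bp) and 8q24.12 (2960 bp). The fifth widest SPDEF peak lay in 14q32.33 (2061 bp). In the mouse list they lay in 1qA5 (4442 bp), 3qF1 (4181 bp), 1qD (3844 bp) and 3qA3 (3519 bp).

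Both human lists were unevenly spread over chromosomes. Chromosomes 12, 20 and 14 held more peaks than their length gives. The GATA6 ratios of observed to expected were 2.06 (95% Poisson interval 1.93 to 2.19), 1.78 (1.61 to 1.97) and 1.68 (1.55 to 1.81). The SPDEF ratios were 2.80 (2.51 to 3.12), 3.15 (2.71 to 3.65) and 2.49 (2.19 to 2.83). Chromosome 13 had the lowest autosomal ratios, 0.312 (0.260 to 0.372) for GATA6 and 0.145 (0.0813 to 0.240) for SPDEF. Chromosome length includes the short arm of chromosome 13, which held 0 peaks; on its long arm the ratios were 0.370 and 0.172. Chromosome 13 was lowest by length only. Per protein-coding gene its ratios were 0.687 and 0.320, and the lowest were those of chromosome 19 for GATA6 (0.239) and chromosome 22 for SPDEF (0.272). With the wider 50% of peaks, by length, chromosome 22 was lowest for GATA6 (0.271, against 0.312 for chromosome 13) and chromosome 13 for SPDEF (0.0775). In the mouse list the highest ratios were 2.19 on chromosome 19, 1.73 on chromosome 11 and 1.62 on chromosome 15.

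**Figure D3:**
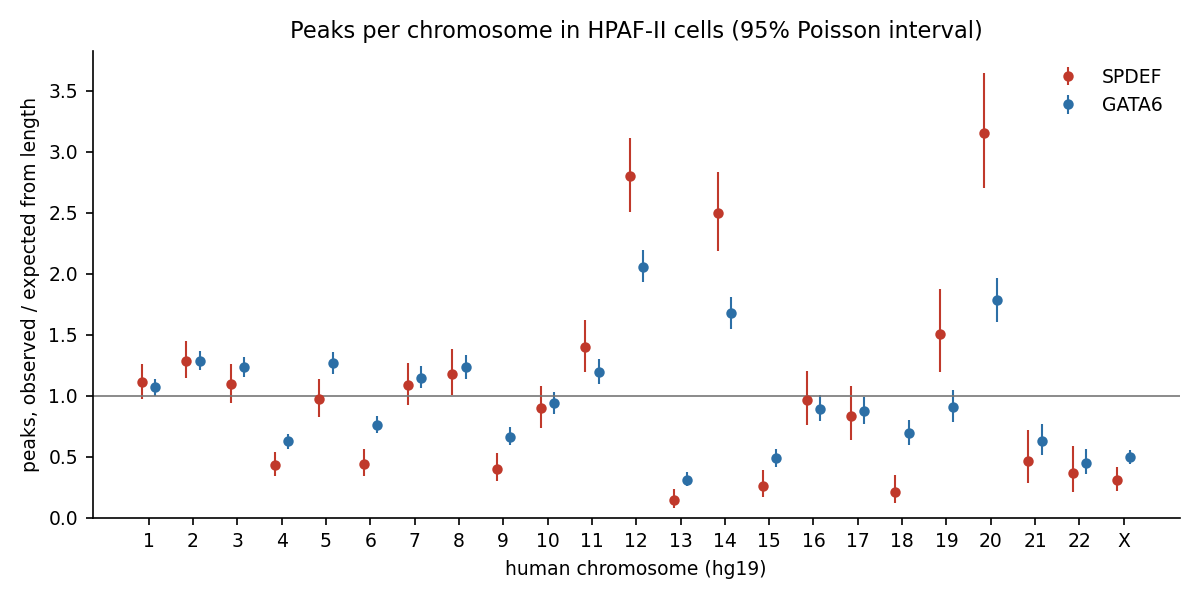
Observed to expected number of peaks (y axis) for chromosomes 1 to 22 and X (x axis) in the SPDEF and GATA6 lists. Points are ratios to the number given by length, bars 95% Poisson intervals; chromosomes 12, 14 and 20 lie above 1 in both lists and chromosome 13 has the lowest autosomal ratios by length, 0.145 and 0.312.

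The share of GATA6 peaks that carried an SPDEF peak also differed between chromosomes. It was highest on chromosome 20 (28.2%, 23.9 to 32.8) and low on chromosomes 18 (5.35%, 2.93 to 9.56) and 13 (5.65%, 2.76 to 11.19). With GATA6 peaks in the wider 50% the lowest share was that of chromosome 13 (6.45%). A permutation test of 5 Mb windows gave p = 1e-04, the smallest possible. The second highest share was that of chromosome 19 (27.03%, 21.14 to 33.85). By length its GATA6 peaks were not raised (ratio 0.908), but its SPDEF peaks were (ratio 1.51, 1.197 to 1.879). Per protein-coding gene both ratios of chromosome 19 lay below 1, at 0.239 for GATA6 and 0.398 (0.315 to 0.495) for SPDEF. Chromosomes 19 and 20 held 80 and 178 SPDEF peaks beside 185 and 387 GATA6 peaks. Chromosomes 18 and 13 held 15 SPDEF peaks each, beside 187 and 124 GATA6 peaks. The share can thus follow the number of SPDEF peaks. How often the factors share sites on a chromosome was not separated from that number. On chromosome 14 155 of 620 GATA6 peaks carried an SPDEF peak, and on chromosome 12 the share was 23.2%.

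At the scale of cytogenetic bands, 145 of 862 bands passed the threshold for GATA6 and 82 for SPDEF, 59 of them in both. With independent lists 13.8 bands would be expected in both (Fisher's exact test, odds ratio 20.7, p = 1.6e-32). The count of 59 includes the overlap of the peaks themselves, so the test gives no separate evidence of shared regions. Fewer bands passed with the wider 50% of each list, 94 for GATA6 and 49 for SPDEF. With the expected number taken from the rate of the chromosome, 119 passed for GATA6 and 46 for SPDEF. Of the bands past the threshold by length, 92 of 145 and 40 of 82 stayed. For both factors, most of the 10 bands with the highest ratio lie on chromosomes 12, 14 or 20. Their ratios by length include the excess of the whole chromosome. The highest SPDEF ratios were in 4p11 (38 peaks against 1.97 expected) and 10q11.21 (41 against 3.41), where all peaks lay within 1 Mb of a centromere band. Next came 12p11.23, 12q13.13, 1q22, 14q22.2, 11q13.1, 14q11.2, 12q13.3 and 20q11.22, at ratios from 11.16 down to 6.79. Counted per protein-coding gene, 3 of these no longer passed the exact Poisson test: 1q22 (1.88, adjusted p = 0.210), 11q13.1 (1.46, adjusted p = 0.438) and 12q13.3 (1.42, adjusted p = 0.816). The ratios of 12q13.13, 14q11.2 and 20q11.22 were then 2.73, 2.50 and 2.47. The highest GATA6 ratios were in 15q22.33, 14q22.2, 12p11.23, 12q21.33, 14q13.3, 3q25.1, 12q24.12, 12q21.2, 1q42.3 and 11q22.2, from 11.6 down to 4.72. Per gene, 11q22.2 no longer passed (2.03, exact Poisson test, adjusted p = 0.0542), 12q24.12 had a ratio of 2.68, and 12q21.33 and 12q21.2 had ratios of 10.02 and 8.92.

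Among the 12 bands fixed in advance, SPDEF peaks exceeded expectation in 4 over all bands and in 5 adjusted over the list alone. In 1q22, the band of MUC1, a membrane mucin, 13 peaks stood against 1.34 expected (ratio 9.67, 95% Poisson interval 5.15 to 16.5, exact Poisson test, adjusted p = 1.7e-07). The ratios were 5.58 in 7q22.1, with MUC3A, MUC12 and MUC17, 4.49 in 3q29, with MUC4 and MUC20, and 11.16 in 12q13.13, with type II keratin genes. In 19q13.2, with CEACAM genes, the ratio was 2.37 (exact Poisson test, adjusted p = 0.104 over all bands and 0.0272 over the list alone). These bands are gene-rich. Counted per protein-coding gene, the SPDEF ratios were 3.13 in 3q29, 2.73 in 12q13.13, 1.88 in 1q22, 1.76 in 7q22.1 and 0.527 in 19q13.2, the last below expectation.

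The band of the gel-forming mucins MUC2, MUC5AC, MUC5B and MUC6, 11p15.5, held 3 SPDEF peaks against 2.51 expected and 6 GATA6 peaks against 9.65. The trefoil factor band 21q22.3 had ratios of 1.61 for SPDEF and 1.31 for GATA6. AGR2 and AGR3, of which AGR2 is a disulfide isomerase of mucus-secreting cells, lie in 7p21.1, with 7 SPDEF peaks (ratio 1.78, exact Poisson test, adjusted p = 0.623) and 47 GATA6 peaks (3.10, adjusted p = 2.1e-09). SPDEF ratios were 1.08 in 6p21.31, the band of SPDEF itself, 0.372 in 18q11.2, that of GATA6, 1.67 in 3q21.2, that of MUC13, and 1.79 in 17q21.2, with type I keratin genes. None of these passed. Per gene, the SPDEF ratios were 2.81 in 7p21.1 and 1.81 in 3q21.2, and lay below 1 in 21q22.3 (0.672), 18q11.2 (0.556), 6p21.31 (0.461), 11p15.5 (0.255) and 17q21.2 (0.251). GATA6 peaks passed in 6 of the 12 bands over all bands and in 7 adjusted over the list alone. Besides 7p21.1, the 6 were 7q22.1 (3.45), 3q29 (3.40), 12q13.13 (3.33), 1q22 (2.71) and 19q13.2 (1.79), and 3q21.2 (2.03) was added over the list alone. Per gene, the GATA6 ratio was 4.90 in 7p21.1, 2.37 in 3q29 and 2.19 in 3q21.2, but 1.09 in 7q22.1 and below 1 in 12q13.13 (0.814), 1q22 (0.526) and 19q13.2 (0.398). The GATA6 ratios were 0.562 in 6p21.31, 1.16 in 18q11.2 and 1.16 in 17q21.2, none of which passed. Per gene they were 0.240, 1.73 and 0.163, and those of 21q22.3 and 11p15.5 were 0.546 and 0.133.

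**Figure D4:**
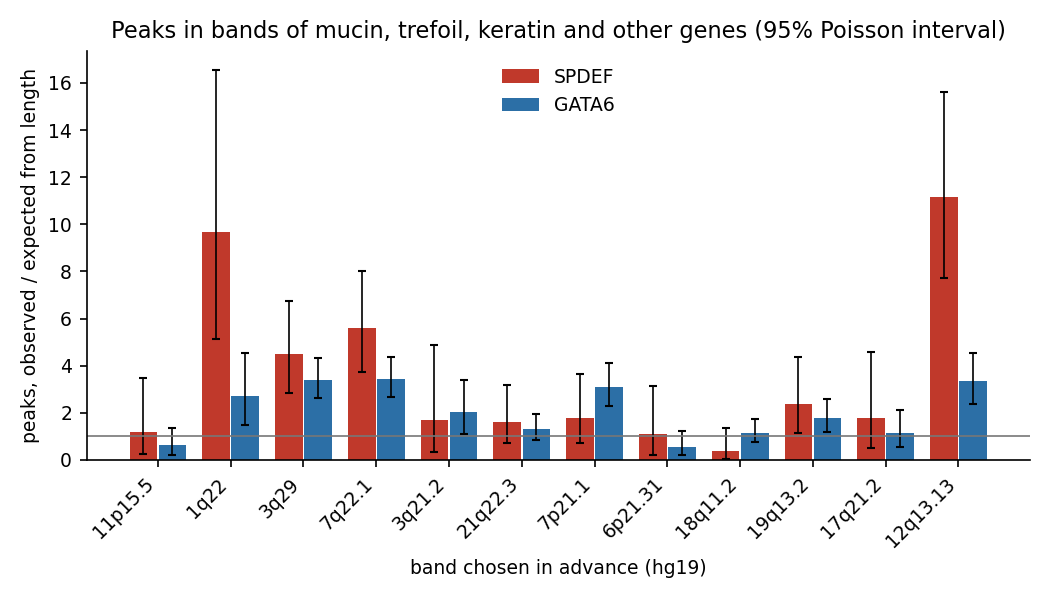
Observed to expected number of SPDEF and GATA6 peaks (y axis) in the 12 bands fixed in advance (x axis), with 95% Poisson intervals; the grey line marks a ratio of 1. The SPDEF ratios are highest in 12q13.13 (11.16) and 1q22 (9.67).

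In 12q13.13, 17 of 34 SPDEF peaks overlapped a GATA6 peak and 15 of 39 GATA6 peaks overlapped an SPDEF peak. The peaks were spread over the band and not confined to 1 site.

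**Figure D5:**
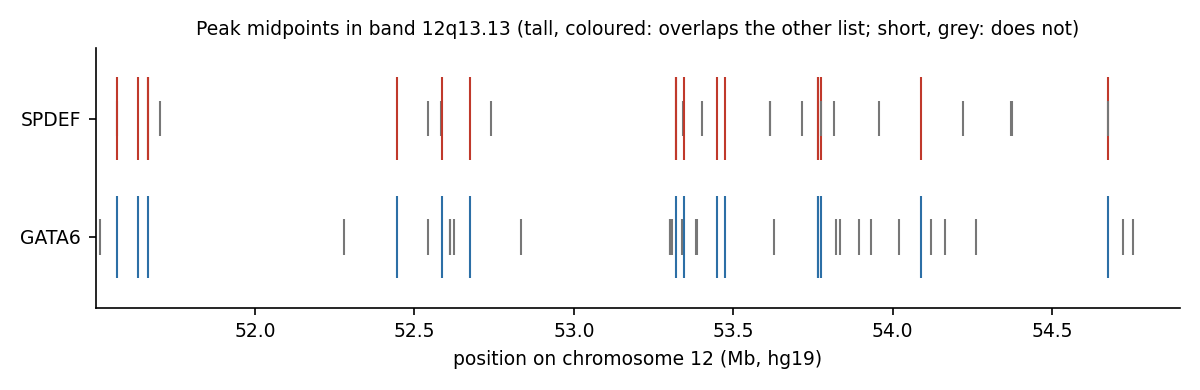
Midpoints of the 34 SPDEF and 39 GATA6 peaks in band 12q13.13 along chromosome 12 (x axis, Mb, hg19). Tall coloured lines are peaks that overlap the other list, 17 for SPDEF and 15 for GATA6, and short grey lines those that do not.

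Gene lists were compared with random gene lists through their bands. For GATA6, bands of endoderm and epithelial transcription factors held 1.45 times the peaks per Mb of random lists (permutation, adjusted p = 0.0066), mucin genes 1.80 times, basal-like PDA subtype genes 1.57 times and epithelial-mesenchymal transition genes 1.39 times (adjusted p = 0.0319 for each). The 14 mucin genes fall in 8 bands and the 23 basal-like genes with a band in 16, so the p-values of these lists may be too small. Classical PDA subtype genes had a ratio of 1.34 (permutation, adjusted p = 0.110). Counted per protein-coding gene, the mucin ratio was 1.07 (permutation, adjusted p = 0.841) and the basal-like ratio 1.32 (adjusted p = 0.554). Transcription factors then had a ratio of 1.70 (permutation, adjusted p = 0.0110) and epithelial-mesenchymal transition genes 1.69 (adjusted p = 0.0495). With the wider 50% of peaks the mucin ratio was 1.70 (permutation, adjusted p = 0.103). The ratio was 1.17 for mucus secretion and goblet cell genes and 0.914 for protein folding genes, and neither passed. The comparison lists of neuronal, blood and immune, pancreatic acinar and islet, and ribosomal protein genes had ratios of 1.06, 1.11, 1.02 and 0.930, and none passed.

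For SPDEF, none of the 11 lists passed. The mucin ratio was 2.37 (permutation p = 0.0140, adjusted p = 0.154), the basal-like ratio 1.62, the epithelial-mesenchymal transition ratio 1.43, the transcription factor ratio 1.41, the classical ratio 1.32 and the mucus secretion ratio 1.21. Protein folding genes had a ratio of 0.965. The neuronal, blood and immune, acinar and islet, and ribosomal lists had ratios of 0.715, 1.23, 0.927 and 1.10. At an unadjusted p under 0.05 stood 2 lists, mucin genes and transcription factors (permutation p = 0.0410). Counted per protein-coding gene, the mucin ratio fell to 1.40 (permutation p = 0.371, adjusted p = 0.697). Transcription factors then reached 1.65 (permutation, adjusted p = 0.0176) and epithelial-mesenchymal transition genes 1.73 (adjusted p = 0.0319).

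The mouse Spdef list addresses the same factor in FC1245 cells and was not compared by position with the human lists. Of 403 mouse bands, 64 passed, and 42 with the wider 50% of peaks. The highest ratio was in 15qF2 (20 peaks against 1.92 expected, exact Poisson test, adjusted p = 1.6e-12), followed by 3qF2.1, 2qC1.2, 6qB2.3, 18qB2, 9qA5.2, 15qE1, 15qE2, 19qC3 and 1qH2.2, at ratios from 5.10 down to 3.56. The 50 peaks in 6qB2.3 (10.3 expected) include neighbouring clusters of 17 and 15 peaks, so its ratio rests largely on 1 place.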

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

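No paired analysis was possible because each target has 1 peak list and no values per replicate. The alternatives with regions near centromeres, chromosomes 12, 14 and 20, peaks under 100 bp, gene counts, stitching gaps and window sizes were chosen after seeing the data. The SPDEF and GATA6 overlap stayed past its threshold under all 15 alternatives run, from 31.1% when 50% of both peaks had to be covered to 70.1% for midpoints within 1 kb, and from 68.0 to 289.5 times random. Differences in median width kept direction and threshold except for shared GATA6 peaks with 50% of both covered, at 20 bp, a rule that excludes wide GATA6 peaks by construction. For shared GATA6 peaks the difference was 168 bp with 1 bp shared, which can favour wide peaks, and 98 bp with midpoints within 1 kb. Its size thus depends on the rule. Bands past the threshold fell with the wider 50% of peaks to 94 for GATA6, 49 for SPDEF and 42 for mouse Spdef, where fewer peaks were tested. With the rate of the chromosome as expectation 119 passed for GATA6, 92 of them among the 145, and 46 for SPDEF, 40 of them among the 82. For mouse Spdef 55 passed, 44 of them among the 64. With gene counts as expectation 203 of 813 bands passed for GATA6, 105 of them among the 145, and 67 for SPDEF, 50 of them among the 82. Of 18 chromosome ratios 6 moved beyond their interval with the wider 50% of peaks, none across 1. Among gene list alternatives 3 calls were gained, 3 lost and 82 unchanged; 1 gain, of mucin genes for SPDEF without chromosomes 12, 14 and 20, came from a lower random rate, since no mucin band lies there. Counts of clusters moved with the stitching gap in 4 of 6 comparisons, and the odds of SPDEF over GATA6 peaks near centromeres fell from 3.06 to 1.40 with stitched peaks counted once. The lower sharing of SPDEF peaks near centromeres with GATA6 was not seen with 1 peak per locus, its widest (odds ratio 1.21), where a cluster counts once. Wider peaks overlapped more often, so picking the widest peak of a cluster can raise that share. Location relative to genes, gene lists near peaks, genes shared between species and motifs were not run. The unknown depth limits what the absence of a peak shows.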

Other observations

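The moves of 10 to 100 kb were planned before the data were examined; the other tests below were chosen after the patterns were seen. After stitching, GATA6 peaks formed 104 clusters of at least 5 peaks, SPDEF peaks 14 and mouse Spdef peaks 27. They held 607 of 10670, 141 of 2775 and 182 of 5719 peaks. The lists differ in length, so numbers of clusters do not compare how strongly peaks gather. Away from centromeres the GATA6 clusters with the most peaks lay in 12p12.1 (chromosome 12, 26253895 to 26281507) and 14q21.3 (chromosome 14, 50439322 to 50490929), with 9 peaks each. The SPDEF cluster with the most peaks there lay in 12q24.31 (chromosome 12, 125401227 to 125425334, 7 peaks, with 4 GATA6 peaks). The mouse list had 2 neighbouring clusters in 6qB2.3, of 17 peaks (chromosome 6, 47737306 to 47781326) and 15 peaks (47652431 to 47686491).

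SPDEF peaks lay on GATA6 peaks far more often than at random. A shared preference for the same broad regions predicts that small moves keep the overlap, but after moves of 10 to 100 kb at most 45 SPDEF peaks overlapped, against 1796. Signal near centromeres, on the mitochondrial genome and at the start of chromosome 1 does not account for it, since 65.7% overlapped without those regions. Cutting in open chromatin whatever the antibody stays open: outside those regions 74.6% of the widest quartile of SPDEF peaks had a GATA6 peak, and without an IgG list and depths it cannot be told apart from shared binding. Binding of both factors at the same sites remains a hypothesis.

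Chromosomes 12, 14 and 20 were rich in peaks of both human lists. Gene density is not the whole cause: per protein-coding gene, the lowest lower bound of the 3 GATA6 ratios was 1.22, and gene-dense chromosome 19 had a GATA6 ratio of 0.239. For GATA6 chromosome 20 then no longer stood out, at 1.35 against 1.64, 1.63, 1.61 and 1.48 on chromosomes 5, 8, 2 and 3, whereas for SPDEF chromosomes 14, 20 and 12 kept the highest ratios (2.86, 2.39 and 2.37). Over 23 chromosomes, genes and GATA6 peaks per Mb had Pearson r = 0.08 (permutation p = 0.710, adjusted p = 0.710; 0.336 without the 2 farthest chromosomes) and Spearman rho = 0.160 (permutation p = 0.464, adjusted p = 0.464); for SPDEF r was 0.26 (permutation p = 0.216, adjusted p = 0.323; 0.435 without those farthest) and rho 0.399 (permutation p = 0.0598, adjusted p = 0.0897). A property shared by both antibodies, such as copy number, may contribute, since unshared peaks of the lists followed the same chromosomes (rho = 0.727, permutation p = 0.00017, adjusted p = 0.00051; r = 0.717, permutation p = 0.00013, adjusted p = 0.00039; 0.626 without the 2 farthest; 3 relations computed). These were 601 SPDEF peaks with no GATA6 peak within 10 kb and 8817 GATA6 peaks that overlapped no SPDEF peak, both outside the regions near centromeres, the mitochondrial genome and the start of chromosome 1. Copy number was not analysed here, and regulatory activity would predict the same.

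Within 1 Mb of a centromere band, 4.94% of the genome, lay 168 of 2775 SPDEF peaks (6.05%) and 220 of 10670 GATA6 peaks (2.06%; Fisher p = 2.0e-24). Of the 168, 103 lay in 7 clusters, and with stitched peaks counted once the shares were 2.51% and 1.81% (Fisher's exact p = 0.0441), both below the share of the genome. The 4.94% includes the centromere bands themselves, and how much of them reads can map to was not examined. Lying below it therefore shows no depletion. That all 7 SPDEF clusters near centromeres held GATA6 peaks separates nothing, since the 7 other clusters did too; edges were then compared instead. Near centromeres 15.48% of 84 overlapping pairs had both edges within 10 bp, against 2.52% of 1744 elsewhere (Fisher p = 7.6e-07), as signal set by the reference sequence, such as repeats, would give. Counted over all peaks, sharing with GATA6 was lower near centromeres (48.8% against 65.7%, Fisher p = 1.3e-05). With the widest peak of each stitched locus it was 70.9% of 55 against 66.7% of 2132 (Fisher's exact p = 0.565). Overlap rose with width, so picking the widest peak of a cluster favours overlap near centromeres. This comparison therefore cannot show that sharing there was equal. Matching edges stayed more frequent, at 5 of 39 against 38 of 1423 (p = 0.00476, Fisher's exact test). From the matching edges alone, reference sequence may set part of this signal. No biological explanation was tested.

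Of the 1828 overlapping pairs, 57 had both edges within 10 bp. The widest of them were those in 1p36.33 and 11p15.4, among the widest SPDEF peaks, followed by 3q11.2 (chromosome 3, 96336132 to 96336975) and 5q31.1 (chromosome 5, 134259485 to 134260303). All of these lay away from centromeres and counted as elsewhere in the comparison of edges. Whether reference sequence sets their signal was not examined, so they are not shown to be sites of either factor. Across overlapping pairs, which are not independent replicates, SPDEF and GATA6 widths had Spearman rho = 0.06.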
